A study of Mus musculus with 9 samples.

How the data were processed

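Skin biopsies of mice were profiled by RNA sequencing in 9 libraries, 3 from healthy controls, 3 after bleomycin and 3 after bleomycin with topical nitrate, and groups were taken from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit and mRNA libraries were made with the SMARTer kit, and the design statement names an Illumina sequencer. Per the submitters' processing notes the genome build was mm10. The aligner, the counting tool, their versions and filters were not given in the sources used here. The authors deposited 1 table of FPKM values per gene and library, with gene identifiers, symbols, coordinates, lengths and biotypes for 54532 genes. In every library the product of FPKM and gene length was a whole multiple of 1 step within 0.01, from which whole reads per gene were recovered. The effective library size behind that step was 0.916 to 1.09 times the reads in the table, an additional scaling by the authors whose method was not given in the sources used here. Recovered reads came to 15804050 to 18352592 per library, and counting error alone allows up to 3 reads where a count of 0 is listed. Where a symbol was given to more than 1 gene, which held for 102 symbols, the gene with the highest mean was used.

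The comparisons, tests, gene lists and the rule for named genes were chosen before the data were examined. Genes with an FPKM of at least 1 in at least 3 of the 9 libraries, 14645 in all, were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, as 1 fit of 3 group means with eBayes (trend and robust), two-sided, for 3 comparisons. A gene that reached 1 FPKM only in the 3 libraries of 1 group was tested because it was high there, so the filter fixed its direction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of a comparison. Negative binomial tests planned for a table of counts were not run, since the table holds FPKM. The 34 gene lists covered matrix, immune and tissue cell types, signalling and RNA quality, and 5 of their genes (Il36g, Il36a, Krt85, Mtarc1 and Mtarc2) were not found under the symbols sought, of which Il36g and Il36a are in the table as Il1f9 and Il1f6 and were left out of their lists. The 33 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01 and again with the correlation estimated from the data, and the counts of called members were also adjusted over each list alone. The genes named were, per comparison, the 10 largest rises and falls among called genes whose groups did not overlap, filled to 5 per direction by the smallest p where fewer passed, up to 4 members of each list with the smallest p, and Il1rl1, Il33, Cd4, Gata3, Foxp3, Il4, Il13, Col1a1, Col3a1, Acta2 and Tgfb1, and the text gives a part of them.

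Fold changes were compared between comparisons by Pearson correlation and covariance across genes, beside values from 100 simulations of unchanged groups. The cross-fitted measure left out each bleomycin library in turn, chose genes by adjusted p from the remaining libraries, and averaged the signed log2 difference between the library left out and each nitrate library. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, only the groups compared in the fit, the replicate number as a block, sample weights (arrayWeights), a minimum absolute log2 fold change of 1, the 200 genes with the smallest p for the cross-fitted measure, and leaving out each library in turn. Voom on the recovered reads, the mean of the hair follicle list as a covariate, leaving out both libraries lowest in that list, also leaving out a control library in the cross-fitted measure, and dropping genes that follow the hair follicle list were added after the data were seen. The test was tried on simulated data with 200 changed genes, where it recovered 57.6% of genes changed by log2 1 and 87.2% of those changed by log2 2 between nitrate and bleomycin. The simulation drew genes independently and took each gene's estimated SD as its true SD. In the data the estimated correlation within a list reached 0.918. These shares may thus not hold for the data, and genes that did not pass may still have changed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.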

Results

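RNA was sequenced from skin biopsies of mice in 3 groups of 3 libraries each. The groups were healthy control skin, skin treated with bleomycin, and skin treated with bleomycin and topical nitrate. Bleomycin is an antibiotic that breaks DNA and is used in mice to model the skin fibrosis of systemic sclerosis. Nitrate is an anion that tissues can reduce to nitrite and nitric oxide. Doses, time points, strain, sex and the number of animals behind the libraries were not given in the sources used here, so p-values measure only the spread between these libraries. The reads recovered from the table came to 15804050, 18352592 and 18001979 in control 1, 2 and 3, 16383602, 16245572 and 17153360 in bleomycin 1, 2 and 3, and 17385342, 17841105 and 17431933 in nitrate 1, 2 and 3. A gene with 0 reads in a library could have had up to 3 by counting error alone.

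The libraries differed in tissue content as well as in treatment. The first and second principal components of the 14645 tested genes held 47.8% and 23.4% of the variance. Genes of the growing (anagen) hair follicle set libraries of one group apart, with a mean log2(FPKM + 1) of 0.31, 3.44 and 5.57 in control 1, 2 and 3, 1.10, 5.20 and 6.42 in bleomycin 1, 2 and 3, and 7.42, 5.33 and 7.94 in nitrate 1, 2 and 3. Transcripts encoded by the mitochondrial genome took 7.48 ± 0.763% of reads in control (SD, n = 3), 3.91 ± 0.222% in bleomycin and 3.81 ± 0.860% in nitrate. Below, FPKM values are means ± SD of 3 libraries, and adjusted p values are Benjamini-Hochberg values over the 14645 genes. Fold changes are differences of log2(FPKM + 1) ± standard error from limma. The added 1 makes them smaller than log2 ratios of FPKM, most so for genes near or below 1 FPKM. Their sizes thus cannot be compared directly between low and high genes. The reads of near-identical genes, among them the Stfa, Sprr, Lce3, S100a, Serpina3, Serpinb3, Defb8, keratin and immunoglobulin constant genes, cannot be assigned with certainty to 1 member, so their single values are uncertain.

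The comparison of bleomycin with control asked what the drug changed in skin. Genes that keratinocytes switch on when the barrier is wounded or inflamed rose strongly. Of 20 measured genes of the stress keratinocyte and barrier repair list, 18 rose and 0 fell (19 rose adjusted over the list alone), with a median log2 fold change of 3.80. Lce3c, a protein of the late cornified envelope, rose from 0.644 ± 0.479 to 24.8 ± 11.04 FPKM (3.93 ± 0.31, adjusted p = 0.00177). Stfa3, an inhibitor of cysteine proteases, rose from 27.7 ± 15.8 to 1181 ± 445 FPKM (5.51 ± 0.51, adjusted p = 0.00253). Sprr1b, which is cross-linked into the cornified envelope, rose from 4.63 ± 5.36 to 232 ± 139 FPKM (5.74 ± 0.81, adjusted p = 0.00822). The camera test called the list higher (adjusted p = 1.37e-15), but adjusted p = 0.224 with an estimated correlation. Outside the list, Chil1, a chitinase-like protein secreted in inflamed tissue, rose from 0.840 ± 0.279 to 69.98 ± 64.3 FPKM (4.91 ± 0.62, adjusted p = 0.00574).

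Most inflammatory genes and some immune cell genes rose beside them. In the inflammatory cytokine and chemokine list 11 of 17 measured genes rose (16 adjusted over the list alone), with a median of 1.53 (adjusted p = 6.62e-12 by camera, adjusted p = 0.224 with an estimated correlation). Il1b, a main inflammatory cytokine, rose from 0.905 ± 0.406 to 28.1 ± 10.02 FPKM (3.89 ± 0.36, adjusted p = 0.00253). Cxcl5, a chemokine that draws neutrophils, rose from 0.129 ± 0.223 to 9.22 ± 4.58 FPKM (3.08 ± 0.36, adjusted p = 0.00474). Cxcl5 and Cxcl2 of this list reached 1 FPKM in the bleomycin libraries alone, so the filter fixed the direction of their change. Of the 14 genes of the neutrophil list only 5 were measured, and all 5 rose (5 adjusted over the list alone, adjusted p = 0.231 with an estimated correlation). Among them were the chemokine receptor gene Cxcr2 (2.66 ± 0.28, adjusted p = 0.00387) and the lectin receptor gene Clec4d (2.09 ± 0.23, adjusted p = 0.00435). The others were Csf3r, S100a8 and S100a9, and which cells expressed these genes was not tested. In the mast cell list 6 of 11 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.353 with an estimated correlation), with Fcer1a, a chain of the IgE receptor, rising from 0.177 ± 0.111 to 6.37 ± 0.749 FPKM (2.64 ± 0.23, adjusted p = 0.00212). Among dendritic cell genes 2 of 13 rose (9 higher and 1 lower adjusted over the list alone, adjusted p = 0.458 with an estimated correlation), among them the integrin gene Itgax (1.71 ± 0.28, adjusted p = 0.0116). Among monocyte and macrophage genes 3 of 20 rose (3 adjusted over the list alone, adjusted p = 0.518 with an estimated correlation). Immediate early genes, which also respond to the handling of samples, averaged 4.50 ± 0.13 in control and 5.76 ± 0.71 in bleomycin in log2(FPKM + 1), and 18 of 20 were higher adjusted over the list alone (7 over all genes).

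Some T cell genes, and Il1rl1 and Il33 of the ST2 axis named in the study's title, rose with bleomycin as well. ST2, encoded by Il1rl1, is the receptor of the alarmin IL-33. Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415 in mm10) rose from 1.09 ± 0.710 to 4.37 ± 0.864 FPKM (1.40 ± 0.26, adjusted p = 0.0187), a gene-level value that does not separate its soluble and membrane-bound forms. Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718) rose from 8.72 ± 1.48 to 41.8 ± 15.97 FPKM (2.07 ± 0.41, adjusted p = 0.0220). Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221), the co-receptor of helper T cells, rose from 0.611 ± 0.272 to 5.02 ± 0.307 FPKM (1.92 ± 0.20, adjusted p = 0.00387), and Trbc2, a constant segment of the T cell receptor, had a fold change of 1.28 ± 0.14 (adjusted p = 0.00435). The T cell list had 7 of 13 genes higher (9 adjusted over the list alone, adjusted p = 0.264 with an estimated correlation). In the ST2 and type 2 cytokine list 7 of 20 were higher (10 adjusted over the list alone, adjusted p = 0.231 with an estimated correlation). The transcription factor gene Foxp3 of regulatory T cells lay below the filter and was not tested, with 0.0931 FPKM in control and 1.04 in bleomycin. Il13 was listed at 0 in control, had 12 reads over the bleomycin libraries and was not tested. Gata3, a regulator of type 2 T cells, did not pass (-0.25 ± 0.33, adjusted p = 0.672), nor did Il4 (adjusted p = 0.995). Gata3 stood at 8.71, 16.3 and 19.7 FPKM in bleomycin 1, 2 and 3, above Cd4 in each. Whether T cells were its source was not tested. The call of Il1rl1 was lost without control 2 (0.0759), control 3 (0.0562), bleomycin 2 (0.0574) and bleomycin 3 (0.0630) and its adjusted p ranged from 0.0118 to 0.0759 over the alternatives. That of Il33 was lost with no filter (0.0506), without control 1 (0.0531), control 2 (0.0904), control 3 (0.0635), bleomycin 1 (0.0694), bleomycin 2 (0.0639) and both control 1 and bleomycin 1 (0.126), over a range of 0.0121 to 0.126.

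Matrix genes went both ways. The main collagen genes of the dermis fell. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) went from 2661 ± 336 to 937 ± 240.3 FPKM (-1.53 ± 0.23, adjusted p = 0.00886). Col1a2 had -1.65 ± 0.23 (adjusted p = 0.00790). Col3a1 went from 1078 ± 174 to 495 ± 131 FPKM (-1.14 ± 0.22, adjusted p = 0.0208). In the fibrillar collagen and crosslinking list 3 of 26 genes rose and 7 fell (3 and 8 adjusted over the list alone), and the list as a whole was not called (adjusted p = 0.297 by camera, 0.730 with an estimated correlation). Among those that rose was Col12a1, a collagen on the surface of fibrils, from 5.37 ± 2.02 to 53.4 ± 20.8 FPKM (3.08 ± 0.36, adjusted p = 0.00483), and P4ha3, a subunit of a collagen proline hydroxylase (1.61 ± 0.18, adjusted p = 0.00435). In the matrix glycoprotein list 9 of 23 rose and 2 fell (12 and 3 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation), with Postn, a matricellular protein of remodelled tissue, going from 56.4 ± 14.9 to 170.4 ± 25.9 FPKM (1.60 ± 0.20, adjusted p = 0.00567). The myofibroblast and TGF-beta list had 5 of 21 genes higher and 1 lower (7 and 2 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation), and Inhba, a subunit of the TGF-beta relative activin, rose (1.53 ± 0.20, adjusted p = 0.00617). Acta2, the smooth muscle actin of myofibroblasts, did not pass (-0.62 ± 0.30, adjusted p = 0.227), nor did Tgfb1 (0.69 ± 0.21, adjusted p = 0.0839). The matrix protease and inhibitor list had 5 of 19 higher and 1 lower (10 and 5 adjusted over the list alone, adjusted p = 0.458 with an estimated correlation). The call of Col3a1 was lost without control 1 (0.0537), control 2 (0.0830), bleomycin 1 (0.0665), bleomycin 3 (0.0688) and both control 1 and bleomycin 1 (0.128), over a range of 0.0121 to 0.128. Leaving out both control 1 and bleomycin 1, the libraries lowest in hair follicle genes, also ended the calls of Col1a1 (0.0816, range 0.00414 to 0.0816), Col1a2 (range 0.00334 to 0.0722), Postn (range 0.00334 to 0.0501), P4ha3 (range 0.00222 to 0.0503) and Inhba (range 0.00284 to 0.0691), each highest in that setting. The log2 fold changes there were -1.47 for Col1a1, -1.57 for Col1a2 and -1.04 for Col3a1, near those with all libraries.

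Some mitochondrial, fat cell, endothelial and fibroblast genes fell too. Of 13 mitochondrially encoded genes 7 fell (12 adjusted over the list alone, median -1.18, adjusted p = 0.264 with an estimated correlation), with a median of -0.55 under quantile normalization. Among them was mt-Co3, a subunit of cytochrome c oxidase (-1.85 ± 0.31, adjusted p = 0.0127). Of 25 fat cell genes 5 fell (15 adjusted over the list alone, median -0.98, adjusted p = 0.292 with an estimated correlation). Of 18 endothelial genes 5 fell (11 adjusted over the list alone, median -0.75, adjusted p = 0.353 with an estimated correlation), such as the transcription factor gene Sox17 (-1.41 ± 0.21, adjusted p = 0.00886). Fibroblast identity genes had 3 of 16 lower (1 higher and 4 lower adjusted over the list alone, adjusted p = 0.406 with an estimated correlation), with Cd34, a surface marker of resting dermal fibroblasts and vessels, at -1.28 ± 0.18 (adjusted p = 0.00786). None of 21 skeletal muscle genes passed limma's test (21 estimates lay below 0, median -1.31, 0 adjusted over the list alone, adjusted p = 0.518 with an estimated correlation). Nor did any of 29 hair follicle genes (29 estimates lay above 0, median 1.11, 0 adjusted over the list alone, adjusted p = 0.0941 by camera, 0.730 with an estimated correlation). Leaving out both control 1 and bleomycin 1 ended the calls of mt-Co3 (range 0.00670 to 0.0989), Sox17 (range 0.00352 to 0.0794) and Cd34 (range 0.00399 to 0.0785).

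**Figure D1:**
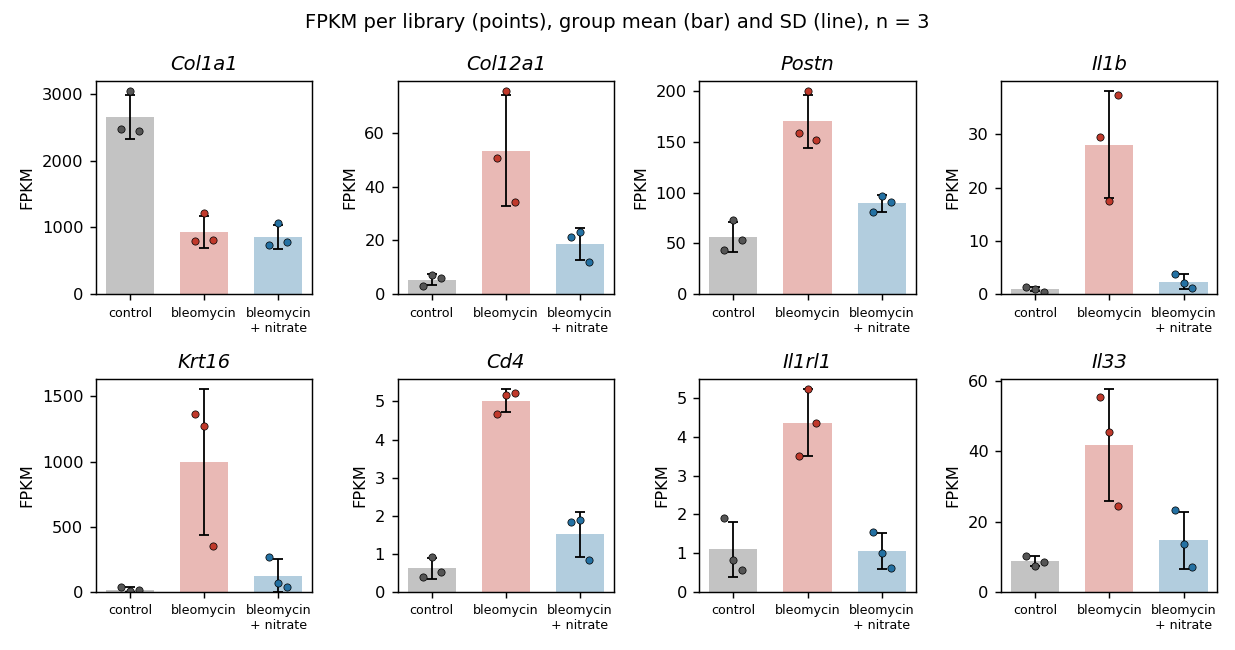
FPKM of 8 genes in control, bleomycin and bleomycin plus nitrate skin on axes that start at 0, with points for libraries, bars for group means and lines for the SD (n = 3). Il1b went from 0.905 ± 0.406 in control to 28.1 ± 10.02 in bleomycin and 2.34 ± 1.40 with nitrate, while Col1a1 stood at 2661 ± 336, 937 ± 240.3 and 859.7 ± 177.

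In all, 1234 of 14645 genes passed limma's test, 694 higher and 540 lower with bleomycin, and 671 of them had an absolute log2 fold change of at least 1. The groups' values did not overlap for 35.7% of genes, where chance gives 10% for 3 libraries against 3. Among the 33 lists tested camera called 19 higher and 7 lower with a preset correlation, and 0 with an estimated correlation. The gene count was 629 without control 1, 334 without control 2, 595 without control 3, 534 without bleomycin 1, 695 without bleomycin 2 and 525 without bleomycin 3. Without both control 1 and bleomycin 1 it was 137.

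The comparison of bleomycin plus nitrate with bleomycin alone asked what topical nitrate changed in skin already exposed to the drug. No single gene passed limma's test, while inflammatory and keratinocyte stress genes had lower values with nitrate in most list members. In the inflammatory list the median log2 fold change was -1.58, with 17 of 17 estimates below 0. Of the 26 genes of that list 17 passed the filter. Cxcl2 and Cxcl5, and Sprr2e of the stress keratinocyte list, reached 1 FPKM in the bleomycin libraries alone. The filter thus fixed their lower values with nitrate, and how many other members entered this way was not counted. Il1b had 28.1 ± 10.02 FPKM with bleomycin and 2.34 ± 1.40 with added nitrate (-3.14 ± 0.36, adjusted p = 0.0619), against 0.905 ± 0.406 in control. Cxcl5 had 9.22 ± 4.58 and 0.331 ± 0.295 FPKM (-2.85 ± 0.36, adjusted p = 0.0619), and Ccl4, a chemokine for monocytes and T cells, had 7.39 ± 2.65 and 0.960 ± 0.717 (-2.12 ± 0.32, adjusted p = 0.0619). The inflammatory list had 0 genes higher and 0 lower over all genes and 15 lower adjusted over the list alone (adjusted p = 1.37e-14 by camera, adjusted p = 0.136 with an estimated correlation). The stress keratinocyte list had a median of -2.08, 17 of 20 estimates below 0 and 16 of 20 genes lower adjusted over the list alone, 0 over all genes (adjusted p = 5.15e-08 by camera, adjusted p = 0.275 with an estimated correlation). Lce3c had 24.8 ± 11.04 and 4.99 ± 1.03 FPKM (-2.04 ± 0.31, adjusted p = 0.0619). All 5 measured genes of the 14 in the neutrophil list were lower adjusted over the list alone, 0 over all genes (median -1.78, adjusted p = 0.270 with an estimated correlation). Among monocyte and macrophage genes 14 of 20 were lower adjusted over the list alone, 0 over all genes (median -1.17, adjusted p = 0.276 with an estimated correlation). Immediate early genes, which also respond to the handling of samples, went the same way, with 18 of 20 estimates below 0 (median -0.91, 10 lower adjusted over the list alone, 0 over all genes, adjusted p = 0.276 with an estimated correlation). Under alternatives Il1b passed without bleomycin 2 (0.0397) and nitrate 1 (0.0290) (range 0.0290 to 0.225 over the alternatives). Ccl4 passed without nitrate 1 (0.0453) (range 0.0453 to 0.225). Cxcl5 passed with the replicate block (0.0461), without bleomycin 3 (0.0292) and nitrate 1 (0.0479) (range 0.0292 to 0.225).

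Most genes of the ST2 and type 2 cytokine list and of the T cell list had lower values with nitrate than with bleomycin alone, and none passed. Il1rl1 had 4.37 ± 0.864 FPKM with bleomycin and 1.05 ± 0.471 with added nitrate (-1.40 ± 0.26, adjusted p = 0.0938), Il33 had 41.8 ± 15.97 and 14.6 ± 8.17 (-1.52 ± 0.41, adjusted p = 0.137), and Cd4 had 5.02 ± 0.307 and 1.51 ± 0.589 (-1.29 ± 0.20, adjusted p = 0.0628). Over the 3 libraries of a group Foxp3, which was below the filter, had 18 reads in control, 216 in bleomycin and 31 in nitrate, while Il13 had 12 in bleomycin and 11 in nitrate. Tnfrsf9, a co-stimulatory receptor carried by activated and regulatory T cells, had 2.84 ± 0.783 and 0.536 ± 0.152 FPKM (-1.30 ± 0.20, adjusted p = 0.0619). Tnfrsf9, and Ccr8 of the ST2 and type 2 cytokine list, reached 1 FPKM in the bleomycin libraries alone, so the filter fixed their direction. Gata3 had higher values with nitrate and did not pass (1.08 ± 0.33, adjusted p = 0.161), nor did Il4 (-0.11 ± 0.16, adjusted p = 0.750). Gata3 was highest in nitrate 1 and 3 (36.8 and 36.6 FPKM). These libraries were also highest in hair follicle genes (list means of 7.42 and 7.94), so Gata3 cannot be read as a value of T cells. The ST2 and type 2 cytokine list had 1 gene higher and 7 of 20 lower adjusted over the list alone and 0 lower over all genes (median -0.69, adjusted p = 0.136 with an estimated correlation). The T cell list had 1 of 13 lower adjusted over the list alone and 0 over all genes (median -0.39, adjusted p = 0.276 with an estimated correlation).

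The main collagen genes lay below control in both bleomycin groups. Col1a1 had 937 ± 240.3 FPKM with bleomycin and 859.7 ± 177 with nitrate (-0.11 ± 0.23, adjusted p = 0.833), and Col3a1 had 495 ± 131 and 414 ± 63.98 (-0.24 ± 0.22, adjusted p = 0.618), while Acta2 (-0.37 ± 0.30, adjusted p = 0.559) and Tgfb1 (-0.57 ± 0.21, adjusted p = 0.213) did not pass either. Other matrix genes had lower values with nitrate. Postn had 170.4 ± 25.9 and 89.4 ± 8.12 FPKM (-0.92 ± 0.20, adjusted p = 0.112), Fn1, which encodes fibronectin, had -1.15 ± 0.25 (adjusted p = 0.115), and Timp1, an inhibitor of matrix proteases, had -2.20 ± 0.50 (adjusted p = 0.120). Lower adjusted over the list alone were 8 of 26 collagen and crosslinking genes (median -0.44), 12 of 23 matrix glycoprotein genes with 1 higher (-0.62), 10 of 19 protease and inhibitor genes (-0.73) and 2 of 21 myofibroblast and TGF-beta genes (-0.37). Over all genes 0 passed in each of these lists, and with an estimated correlation the adjusted p was 0.276 for the collagen, glycoprotein and myofibroblast lists and 0.275 for the protease list.

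Hair follicle and sebaceous gland genes had higher values with nitrate. Of 29 hair follicle genes 29 had estimates above 0, with a median of 3.05 (0 passed over all genes, 1 adjusted over the list alone, adjusted p = 7.27e-07 by camera, adjusted p = 0.494 with an estimated correlation), yet the bleomycin libraries alone spanned 1.10 to 6.42 in the mean of that list. Lgr5, a marker of hair follicle stem cells, had 1.97 ± 0.494 and 5.04 ± 0.934 FPKM (1.03 ± 0.17, adjusted p = 0.0781). Sebaceous gland genes had a median of 0.96 with 14 of 14 estimates above 0 (0 passed over all genes, 1 adjusted over the list alone, adjusted p = 0.290 with an estimated correlation), among them Scd3, a lipid desaturase of that gland (2.29 ± 0.54, adjusted p = 0.123). Skeletal muscle genes had a median of -0.66, fat cell genes -0.42 and mitochondrially encoded genes -0.07, with 0 called in each list, 0 adjusted over each list alone, and adjusted p = 0.745, 0.517 and 0.875 with an estimated correlation. With the mean of the hair follicle list as a covariate, an alternative added after the data were seen, the mitochondrial median was 0.04. Endothelial genes had a median of -0.11 and a mean of 0.01, which differ in sign (0 called, 0 adjusted over the list alone, adjusted p = 0.878 with an estimated correlation).

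The count of genes past the threshold was 0 by limma on log2(FPKM + 1) and 0 by voom. At an unadjusted p under 0.05 there were 2624 genes by limma and 2681 by voom. Splits of the same libraries that mixed bleomycin and nitrate gave 185 to 2011 such genes by limma. The smallest adjusted p was 0.0619, and 111 genes with lower and 29 with higher values had an adjusted p under 0.10. Those with the smallest p included Gpr35, a G protein-coupled receptor gene of immune cells (-1.25 ± 0.15, adjusted p = 0.0619), and Hoxb6, a homeobox gene (1.37 ± 0.21, adjusted p = 0.0619). The groups' values did not overlap for 21.2% of genes, where chance gives 10%. Camera called 21 lists lower and 2 higher with a preset correlation and 0 with an estimated correlation. The gene count was 4 without bleomycin 1, 13 without bleomycin 2, 4 without bleomycin 3 and 37 without nitrate 1, and Gpr35 passed with the replicate block (0.0461) and without nitrate 1 (0.0442) (range 0.0442 to 0.225 over the alternatives).

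**Figure D2:**
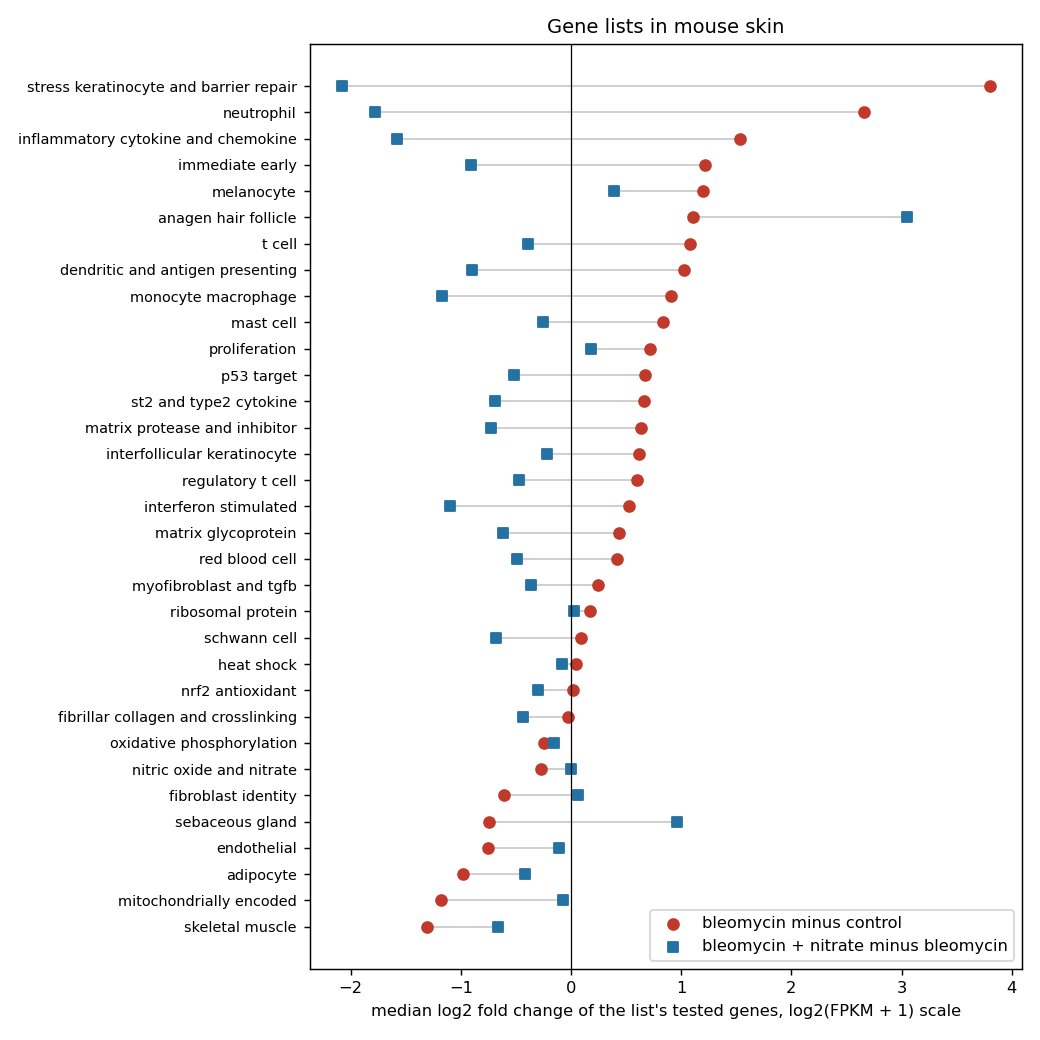
Median log2 fold change on the log2(FPKM + 1) scale (horizontal axis) of each of 33 gene lists (vertical axis), for bleomycin minus control (circles) and bleomycin plus nitrate minus bleomycin (squares). The stress keratinocyte list had the highest circle, at 3.80, with its square at -2.08, and the hair follicle list the highest square, at 3.05.

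The comparison of bleomycin plus nitrate with control asked how far treated skin still differed from healthy skin. Some keratinocyte stress genes passed above control and some collagen genes below it, while no gene of the inflammatory and ST2 lists passed limma's test. Of 20 stress keratinocyte genes 5 rose (12 adjusted over the list alone, median 2.13, adjusted p = 3.27e-07 by camera, adjusted p = 0.579 with an estimated correlation). Stfa3 rose from 27.7 ± 15.8 to 195 ± 59.4 FPKM (2.94 ± 0.51, adjusted p = 0.0193). Sprr4, another precursor of the cornified envelope, is not in that list. It rose from 74.9 ± 25.6 to 646 ± 158 FPKM, beyond its 304 ± 109 with bleomycin alone (3.12 ± 0.35, adjusted p = 0.00761). Col1a1 went from 2661 ± 336 to 859.7 ± 177 FPKM (-1.64 ± 0.23, adjusted p = 0.0127), and Pcolce, an enhancer of procollagen processing, fell as well (-1.36 ± 0.15, adjusted p = 0.00761). In the collagen and crosslinking list 1 of 26 rose and 11 fell (1 and 12 adjusted over the list alone, adjusted p = 0.649 with an estimated correlation). None of 17 inflammatory genes (0 adjusted over the list alone, median 0.07, -0.07 under quantile normalization) and none of 20 ST2 and type 2 cytokine genes (0 adjusted over the list alone, median -0.02) passed limma's test, with adjusted p = 0.837 and 0.980 with an estimated correlation. Il1rl1 had 1.09 ± 0.710 FPKM in control and 1.05 ± 0.471 with nitrate (adjusted p = 0.996), Il33 had 0.55 ± 0.41 (adjusted p = 0.385), and Cd4 had 0.63 ± 0.20 (adjusted p = 0.0827, passing with sample weights (0.0411), range 0.0411 to 0.383 over the alternatives). Fcer1a, the IgE receptor chain, rose from 0.177 ± 0.111 to 3.28 ± 1.49 FPKM (1.81 ± 0.23, adjusted p = 0.0113). The call of Stfa3 was lost without control 1 (0.0575), control 2 (0.0569), nitrate 3 (0.0546), with the hair follicle covariate (0.0948) and without both control 1 and bleomycin 1 (0.0733) (range 0.0170 to 0.0948 over the alternatives). That of Col1a1 was lost without control 1 (0.0513), control 2 (0.0569), with the hair follicle covariate (0.0975) and without both control 1 and bleomycin 1 (0.0703) (range 0.00908 to 0.0975). Pcolce lost its call with the hair follicle covariate (0.0584) and without both control 1 and bleomycin 1 (0.0612) (range 0.00573 to 0.0612). Fcer1a lost its call without control 2 (0.0552), with the hair follicle covariate (0.0834) and without both control 1 and bleomycin 1 (0.0688) (range 0.00881 to 0.0834).

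Some tissue markers differed as well. Of 25 fat cell genes 15 fell (22 adjusted over the list alone, median -1.55), among them Adrb3, the beta-3 adrenergic receptor (-2.33 ± 0.38, adjusted p = 0.0176). Of 13 mitochondrially encoded genes 9 fell (13 adjusted over the list alone, median -1.26, -0.65 under quantile normalization). Of 18 endothelial genes 8 fell (13 adjusted over the list alone, median -0.95), and of 21 skeletal muscle genes 4 (14 adjusted over the list alone, median -1.94), such as Myh4, a fast myosin heavy chain (-4.23 ± 0.70, adjusted p = 0.0176). With an estimated correlation the adjusted p was 0.579 for the fat cell and mitochondrial lists and 0.649 for the endothelial and muscle lists. Hair follicle genes had a median of 4.28, with 29 of 29 estimates above 0 and 1 passing (1 adjusted over the list alone, adjusted p = 0.649 with an estimated correlation), which was Lgr5 (1.07 ± 0.17, adjusted p = 0.0167). The call of Adrb3 was lost without control 1 (0.0530), control 2 (0.0711), with the hair follicle covariate (0.0584) and without both control 1 and bleomycin 1 (0.0666) (range 0.0123 to 0.0711 over the alternatives). Myh4 lost its call without control 1 (0.0569), control 2 (0.0751), nitrate 3 (0.0555) and with the hair follicle covariate (0.145) (range 0.00775 to 0.145). Lgr5 lost its call without control 1 (0.0612), control 2 (0.0686), nitrate 3 (0.0602), with the hair follicle covariate (0.118) and without both control 1 and bleomycin 1 (0.0714) (range 0.0102 to 0.118). In all 1249 genes passed limma's test, 532 higher and 717 lower than in control. Values did not overlap for 34.8% of genes, where chance gives 10%. The gene count was 83 without control 1, 45 without control 2, 711 without control 3, 642 without bleomycin 3, 474 without nitrate 1, 2882 without nitrate 2 and 170 without nitrate 3. It was 9 with the hair follicle covariate and 23 without both control 1 and bleomycin 1.

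**Figure D3:**
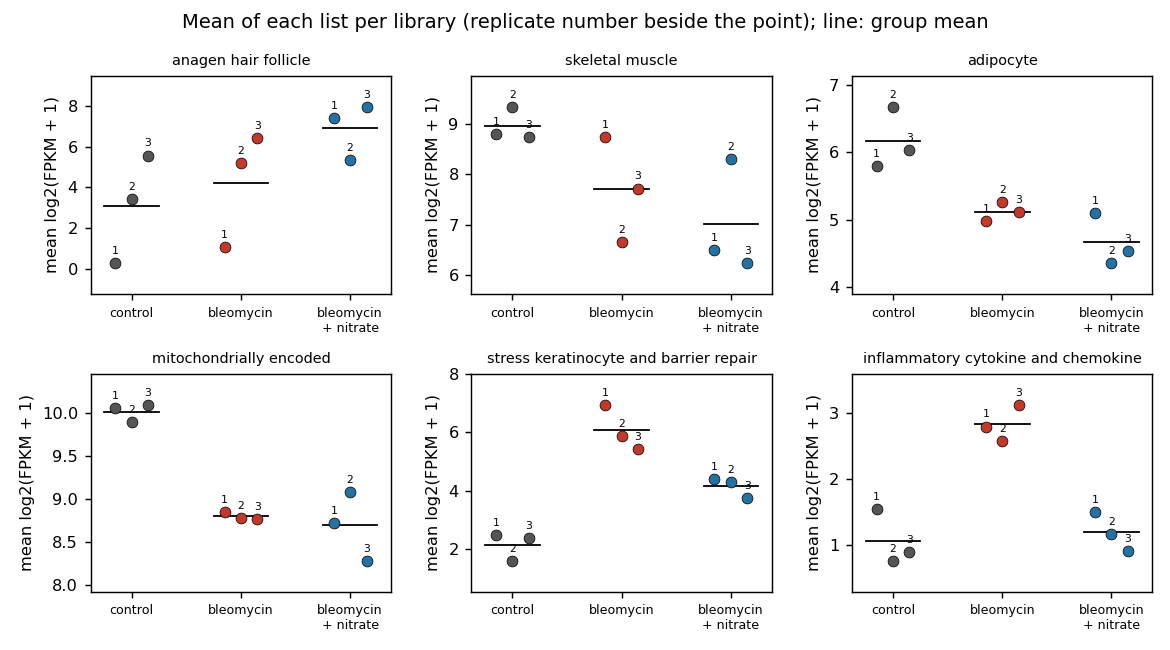
Mean log2(FPKM + 1) of 6 gene lists (vertical axis) in each library of the 3 groups (horizontal axis), with replicate numbers beside the points and a line at each group mean. Hair follicle genes ranged from 0.31 in control 1 to 7.94 in nitrate 3, and the stress keratinocyte list averaged 2.15 ± 0.47 in control, 6.09 ± 0.78 in bleomycin and 4.15 ± 0.36 with nitrate (SD, n = 3).

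Whether nitrate moved the bleomycin response back toward control was measured across genes, which are not independent replicates. The fold changes of bleomycin minus control and nitrate minus bleomycin had a Pearson r of -0.279, but sharing the bleomycin libraries gives -0.499 for unchanged groups in 100 simulations. The covariance was -0.0928 against a simulated -0.0563. A cross-fitted measure avoids this sharing by choosing genes without 1 bleomycin library and then comparing that library with the nitrate libraries. On it, the 538 to 1216 chosen genes lay 0.31 ± 0.13 log2 units nearer to control with nitrate than in the bleomycin library left out (mean ± SD of 3 folds). All 9 of 9 pairs of libraries were above 0, from 0.02 to 0.53. It was 0.63 for genes that bleomycin raised and -0.02 for genes that it lowered. The latter is a mean of folds of both signs. For lowered genes the library left out minus nitrate was 0.228, -0.0958 and -0.0855 in the folds of bleomycin 1, 2 and 3, where values below 0 lie toward control. The folds share libraries, so no test was made. Without control 1, 2 or 3 in turn the value was 1.29, 1.14 and 1.04, and without bleomycin 1, 2 or 3 it was 1.03, 1.87 and 0.61. Some of these folds rest on few genes. Without control 1, 2 or 3 the fold of bleomycin 3 chose 2, 5 and 1 genes, and the other folds averaged 0.66, 0.79 and 0.31. Without bleomycin 1 or 2 a fold chose 20 genes. Of the 694 genes called higher with bleomycin 222 were also called higher with nitrate than in control, and of the 540 called lower 335 were also called lower. Lists independent of each other would share 25.2 and 26.4 genes. Both comparisons share their controls. In 100 simulations of unchanged groups with shared controls the overlap was 0, but such groups give few calls by construction. What this sharing adds to the overlap of changed groups was thus not tested.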

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

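The alternatives by voom, with the hair follicle covariate, without both libraries lowest in hair follicle genes, with a control also left out and without genes that follow the hair follicle list were chosen after the data were seen, and the others before the data were examined. Counts of genes changed by bleomycin stayed within 1.5 times of 1234 under pseudocounts of 0.1 and 0.5, both other scalings, only the groups compared in the fit (1589), voom (1125) and the hair follicle covariate (957). They were 676 with no filter, 747 with a mean FPKM of at least 5, 1947 with sample weights, 671 with a minimum log2 fold change of 1, 137 without both control 1 and bleomycin 1, and 334 to 1539 leaving out 1 library. For nitrate against bleomycin the count of 0 by limma (2624 at an unadjusted p under 0.05) stood under every alternative except the replicate block, with 10, and leaving out 1 library, with 0 to 37. For nitrate against control 1249 became 294 with no filter, 306 with only the groups compared, 2085 with sample weights, 594 with a minimum log2 fold change of 1, 9 with the hair follicle covariate, 23 without both control 1 and bleomycin 1, and 45 to 2882 leaving out 1 library. Fewer libraries or more genes tested account for part of this by construction, and otherwise the cause was not tested. The counts of lists called, 26, 23 and 17, became 0, 0 and 0 with an estimated correlation, and stayed within 1.5 times under the other alternatives.

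Whether the replicate numbers pair the libraries stays open. After group means were removed 5 of 9 same-numbered pairs correlated above 0.1, over a range of -0.39 to 0.52. Of the 9 libraries 5 correlated best with one of their own number. With the replicate block the counts were 1039, 10 and 1067. The correlation of fold changes (-0.279) was -0.392 without both control 1 and bleomycin 1 and -0.417 to -0.115 leaving out 1 library. The cross-fitted value of 0.31 was 0.146 with no filter, 0.530 with the 200 genes with the smallest p, 1.16 with a control also left out (0.586 without 3 of 9 folds that chose 1 to 5 genes), and 0.233 to 1.87 leaving out 1 library, above 0 in each. The cause was not tested. Not run for the cross-fitted value were the replicate block, voom and leaving out both control 1 and bleomycin 1. Sample weights, the fit of only the groups compared, the hair follicle covariate and a minimum log2 fold change of 1 were not run for it or for the correlation, nor the last for lists. Negative binomial tests planned for counts were not run.

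Changes of sign were seen in genes named here that had not passed. For Gata3 in bleomycin against control the log2 fold change was 0.00723 without both control 1 and bleomycin 1 and -0.471 to 0.0755 leaving out 1 library. For Il4 in bleomycin against control the log2 fold change was -0.0278 under quantile normalization, -0.0195 without both control 1 and bleomycin 1 and -0.135 to 0.104 leaving out 1 library. For Col1a1 in nitrate against bleomycin the log2 fold change was -0.277 to 0.0874 leaving out 1 library. For Il1rl1 in nitrate against control the log2 fold change was 0.0248 with a pseudocount of 0.1, 0.00536 with a pseudocount of 0.5, 0.133 with sample weights, 0.0544 by voom, 0.178 with the hair follicle covariate, 0.258 without both control 1 and bleomycin 1 and -0.189 to 0.258 leaving out 1 library. For Il4 in nitrate against control the log2 fold change was 0.0456 with the hair follicle covariate. For Tgfb1 in nitrate against control the log2 fold change was -0.0764 to 0.284 leaving out 1 library. The cause was not tested. Of the genes named in the text 26 of 31 calls in bleomycin against control and 2 of 19 in nitrate against control passed in every fit that left out 1 library.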

Other observations

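The tests of fibroblast share, of collagen scaling, of hair follicle stage, of immune cell share, of both explanations for the return of raised genes and of other splits were chosen after the data were seen, and that of inflammatory gene scaling before. Immediate early genes, which cells switch on within minutes of stress, had 7 of 20 higher in bleomycin than in control (18 adjusted over the list alone, adjusted p = 0.292 with an estimated correlation), among them Socs3, a brake on cytokine signalling (2.19 ± 0.29, adjusted p = 0.00603). With nitrate against bleomycin 10 were lower adjusted over the list alone and 0 over all genes (median -0.91, adjusted p = 0.276 with an estimated correlation). Targets of p53, the DNA damage response factor, had 9 of 22 higher with bleomycin (13 adjusted over the list alone, adjusted p = 0.292 with an estimated correlation), with Pmaip1, a promoter of apoptosis, rising from 1.61 ± 0.407 to 11.6 ± 1.85 FPKM (2.27 ± 0.16, adjusted p = 0.00141) and standing at 3.98 ± 0.642 with nitrate (-1.33 ± 0.16, adjusted p = 0.0619). Interferon-stimulated genes had 0 of 26 called with bleomycin by limma, 0 adjusted over the list alone and a median of 0.53 (adjusted p = 0.641 with an estimated correlation), and with nitrate against bleomycin 12 were lower adjusted over the list alone and 0 over all genes (median -1.09, adjusted p = 0.325 with an estimated correlation). Libraries of one group stood apart in this list. Its means were 3.95, 2.61 and 2.78 in control 1, 2 and 3, 3.75, 3.59 and 3.84 in bleomycin 1, 2 and 3, and 3.46, 2.26 and 1.90 in nitrate 1, 2 and 3. Regulatory T cell genes had 2 of 7 higher with bleomycin (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.292 with an estimated correlation), and of the 3 measured B and plasma cell genes, too few to test as a list, 2 rose (2 higher and 1 lower adjusted over the list alone). Pmaip1 passed in nitrate against bleomycin without nitrate 1 (0.0418) (range 0.0418 to 0.225 over the alternatives).

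In bleomycin against control, interfollicular keratinocyte genes had 5 of 20 higher and 2 lower (10 and 3 adjusted over the list alone, median 0.62, adjusted p = 0.458 with an estimated correlation). Sebaceous gland genes had 1 of 14 higher and 2 lower (1 and 4 adjusted over the list alone, adjusted p = 0.563 with an estimated correlation), with Scd3 going from 148 ± 39.5 to 16.3 ± 12.05 FPKM and standing at 77.04 ± 38.4 with nitrate. Nitric oxide and nitrate genes had 2 of 19 higher and 2 lower (3 and 4 adjusted over the list alone, adjusted p = 0.446 with an estimated correlation), among them Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase (-1.40 ± 0.18, adjusted p = 0.00601, range 0.00288 to 0.0641, lost without both control 1 and bleomycin 1 (0.0641)). In nitrate against bleomycin that list had 0 called (1 lower adjusted over the list alone) and a median of 0.00 beside a mean of -0.04, which differ in sign (adjusted p = 0.840 with an estimated correlation). NRF2 antioxidant genes had 2 of 24 higher and 1 lower with bleomycin (3 and 2 adjusted over the list alone, adjusted p = 0.730 with an estimated correlation), heat shock genes 1 of 14 higher (2 adjusted over the list alone, adjusted p = 0.680 with an estimated correlation) and Schwann cell genes 1 of 11 higher (1 adjusted over the list alone, adjusted p = 0.876 with an estimated correlation). No gene passed limma's test in the melanocyte (of 8, 3 higher adjusted over the list alone, adjusted p = 0.518 with an estimated correlation) and proliferation (of 22, median 0.72, adjusted p = 0.518 with an estimated correlation) lists. The same held in the oxidative phosphorylation (of 24, median -0.24, adjusted p = 0.644 with an estimated correlation), ribosomal protein (of 26, median 0.17, adjusted p = 0.619 with an estimated correlation) and red blood cell lists (of 7, median 0.41, adjusted p = 0.711 with an estimated correlation). The proliferation list and these 3 had 0 adjusted over the list alone. In nitrate against control the median, mean and test of a list differed in sign for the myofibroblast (-0.20, 0.06, lower), heat shock (0.11, -0.01, higher) and dendritic cell lists (0.08, 0.02, lower).

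The main dermal collagens were lower after bleomycin while other matrix genes were higher. A lower share of fibroblast RNA stays open for the collagens, since 13 of 16 fibroblast identity genes had estimates below 0 (median -0.61). That 12 of 65 tested genes of the collagen, glycoprotein and fibroblast lists were called higher and 12 lower is part of the pattern itself, with genes picked by their calls, and decides nothing for the collagens. Scaling was argued against by a median of -1.25 for Col1a1, Col1a2 and Col3a1 under quantile normalization. Hair follicle stage was argued against by -1.52 with the hair follicle covariate. Median-of-ratios scaling hardly changed the values (-1.527 for Col1a1 with and without it) and so adds little. FPKM on plain read totals, without the authors' additional scaling, were not run. Time after injury and depth of the biopsies were not tested. The pattern may also reflect fibroblasts that exchanged bulk collagen synthesis for a repair programme, a hypothesis found on these libraries and not tested.

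Inflammatory and stress keratinocyte genes had lower values with nitrate although no gene passed. With the hair follicle covariate 99.9% of the inflammatory list's median change was left, and the stress keratinocyte median was -1.64 in place of -2.08. Under the other scalings, of which median-of-ratios hardly changed the values, at least 99.5% of the inflammatory change was left. A lower share of immune cells stays open. The stress keratinocyte list, fixed before the data were examined, had a median of -2.08 with 17 of 20 estimates below 0. Its lower values are part of the pattern itself and decide nothing about that share. Members of that list that immune cells may also express, such as Stfa3, were not told apart by source. Handling of the samples stays open as well, here and for the rise of inflammatory genes with bleomycin, since immediate early genes, a sign of it, also had lower values with nitrate (18 of 20 estimates below 0). Their means were 6.22, 4.95 and 6.12 in bleomycin 1, 2 and 3 and 4.70, 4.77 and 4.56 in nitrate 1, 2 and 3, beside 2.80, 2.57 and 3.13 and 1.51, 1.18 and 0.91 for inflammatory genes. A milder inflammatory and wound response under nitrate is a hypothesis beside these that the values may fit. The stage of the wound at biopsy and the number of animals behind the libraries were not tested.

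Genes that bleomycin raised lay nearer to control with nitrate, by 53.2% ± 2.71 of the way (SD of 3 folds). Genes that it lowered did so by 7.86% ± 12.7. The folds share the nitrate and control libraries, so these SDs hold no spread between nitrate libraries and understate the uncertainty. Without the 9452 genes that followed the fat, muscle or hair lists within groups the shares were 67.6% and 13.7% ± 14.3. Lowered genes came to 8.04% under median-of-ratios scaling, which hardly changed the values, and to 6.90% under quantile normalization. These values argue against scaling, for the scalings run, as the whole cause. They cannot decide on fat, muscle and hair content. Genes were screened by differences within groups, which took out 9452 of 14645 genes and cannot see content that differs between groups. The fat list averaged 6.17 in control, 5.12 in bleomycin and 4.66 with nitrate, and the muscle list 8.97, 7.70 and 7.01. The hair follicle list averaged 3.10, 4.24 and 6.90. Content of other cell types, immune cells among them, was not tested here and stays open. The measure was changed once after its values were seen, from genes past the threshold to the 200 with the smallest p, since a fold had no lowered genes; before the change it gave 52.1% for raised and 9.79% ± 17.05 for lowered genes over 2 folds, and under quantile normalization 52.2% and -19.1% ± 38.2 over 3 folds. Nitrate may have acted on what bleomycin switched on rather than on what it switched off, which is a hypothesis. Whether lowered genes recover at a later time was not tested.

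The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. In bleomycin against control 1 split, the real one, gave as many genes as 1234, and the highest other gave 1, while 1 gave as many lists as 26, and the highest other gave 19. In nitrate against bleomycin all 10 gave as many genes as 0, which limma found beside 2624 genes at an unadjusted p under 0.05 and 0 by voom, and the highest other gave 131, while 1 gave as many lists as 23, the highest other 18. At an unadjusted p under 0.05 the other splits gave 185 to 2011 genes, against 2624 in the real one. The split with 131 genes, also the one with 2011, put bleomycin 1, bleomycin 3 and nitrate 2 together. It points to a structure of the samples that crosses the groups. Bleomycin 1, bleomycin 3 and nitrate 2 were the libraries higher in skeletal muscle genes, with list means of 8.75, 7.72 and 8.31. Those of bleomycin 2, nitrate 1 and nitrate 3 were 6.65, 6.49 and 6.23. Oxidative phosphorylation genes lay the same way (6.16, 6.02 and 6.09 against 5.69, 5.57 and 5.71). In nitrate against control 1 split gave as many genes as 1249, the highest other 0, and 3 gave as many lists as 17, the highest other 18.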
